A study of Caenorhabditis elegans with 2 samples.

How the data were processed

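The data are transcription factor ChIP-seq of whole Caenorhabditis elegans L4 hermaphrodites, fragmented by sonication and precipitated with an antibody against GFP, per the labels. The antibody field of the labels names DAF-16 itself, which is read here as the target. Biological replicates 1 and 2 of the labels were taken as 2 samples of 1 group, and no other group or control library was analysed here. The deposited file lists name a control library in the derivation of the peak lists. Peak lists were deposited for the genome builds ce11 and ce10, each as a list for replicate 1, a list for replicate 2, a list called on both replicates pooled and a list thresholded on the irreproducible discovery rate (IDR). The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here.

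The deposited lists give for each peak the signal of the authors' caller, a value that is never negative and whose scale and depth scaling are not given in the sources used here. It was used only to describe, rank or filter peaks within a list, and it has no SD. The deposited lists also hold the −log10 of a q-value, which had the same top value in all IDR peaks (q = 1.27e-04) and was therefore not used to rank them. The other deposited column used was the position of the summit within each peak. The replicate and pooled lists contain many weak peaks, so their entries are called candidates here. In both builds the IDR list was found to consist of the strongest peaks of the pooled list by signal, 2563 on ce11 and 3353 on ce10. Most candidates had one width, 436 bp, so positions were taken from summits. Because the files hold no read counts, depth and counting errors of single peaks are unknown, and the intervals given are Wilson 95% intervals of shares of peaks or genes.

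All peak ends of the ce11 lists lay within the chromosome lengths of the reference sequence used here, WBcel235, which is the assembly that ce11 names, and genes came from Ensembl release 115. Coordinates are 1-based ce11 positions. The ce10 lists were used for peak counts, replicate agreement and chromosome shares, and no coordinate was carried between builds. Peaks of different lists were matched when their summits lay within 100 bp. IDR peaks were compared with pooled candidates farther than 100 bp from any IDR summit. Promoter windows ran from 1000 bp upstream to 200 bp downstream of an annotated 5' end of any gene for peak shares, and of the most upstream 5' end for gene lists. Motifs and all sequences of 7 bases were searched on both strands within 100 bp of the summit and counted once per peak. Motif shares were also compared with each flank of the same peaks 400 to 600 bp away, and each flank was tested apart because both together are longer than the summit window.

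Shares were compared by two-sided Fisher's exact tests, flanks by two-sided exact sign tests and chromosomes by two-sided exact binomial tests. Log2 odds ratios are given ± their SE by Woolf's formula, with 0.5 added to each cell when a cell was 0. Adjusted p-values are Benjamini-Hochberg values over the 10 motifs, the 24 gene lists, the 7 noncoding classes, the 8192 sequences, the location classes or the chromosomes, with a threshold of 0.05. The gene lists covered DAF-16 class I and class II targets, insulin and TOR signalling, insulin-like peptides, tissue markers (body wall muscle, pharyngeal muscle, intestine, hypodermis and cuticle, neurons, germline), ribosomal proteins, proteasome, autophagy and lysosome, chaperones, oxidative stress defence, respiratory chain, carbon metabolism, translation factors, nuclear hormone receptors, homeobox genes, collagens, C-type lectins, chemosensory receptors and F-box, MATH or BTB genes. The symbols hsp-16.49 and sodh-1 of the class I list were not found in the annotation used here. The background of a gene list was the set of nuclear protein-coding genes with a candidate in the window. The mitochondrial genome was kept in the location and motif tests and left out of the gene and chromosome tests.

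The tests, gene lists, windows, most changes of setting and the rule for naming genes were fixed before the data were examined. The rule named the genes at the 25 strongest IDR peaks, up to 4 bound members of each list with the strongest peaks, and sod-3, mtl-1, hsp-12.6, daf-16, daf-2, myo-3, unc-54, unc-119, pqm-1 and dod-24 whatever their values. Other named genes were chosen after their values were seen. The changes of setting fixed then were summit distances of 50 and 200 bp, a reciprocal overlap of 50%, wider and narrower promoter and motif windows, other backgrounds and motif forms, the IDR peaks with at least the median signal (called the stronger IDR peaks), IDR peaks matched in both replicates, and each replicate left out in turn, for which the 2563 strongest candidates of the other replicate took the place of the IDR peaks. Repeats of the tests without the mitochondrial genome, with protein-coding starts alone, without peaks at small RNA genes, without peaks holding a 31-base sequence that recurs in the genome, without peaks holding a dosage compensation motif core, and, for the X chromosome, with matched candidates were added after seeing the data.

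On simulated data, the test over 8192 sequences made 0 calls with labels drawn at random and ranked a planted sequence at the top. Both simulated classes came from candidates outside the IDR list. The simulation therefore does not cover differences in location or base composition between IDR peaks and the other candidates. For the gene lists, 1 of 100 random draws among the 6580 genes called any list, and 97.5% of changed lists were recovered with 8 lists of 30 genes bound at 3 times the background share. Several lists had fewer genes with a candidate, such as 12 class I targets and 9 germline genes, and some genes share a peak. Recovery of such lists was not simulated. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.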

Results

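The series profiled the chromatin binding of DAF-16, the FOXO transcription factor of Caenorhabditis elegans that acts downstream of the insulin receptor DAF-2, by chromatin immunoprecipitation and sequencing. Whole L4 hermaphrodites were collected 54 hours after release from starvation-synchronised L1 larvae. The strain, ZM7247, carries a daf-16 deletion allele, a reduced-function daf-2 allele and a transgene in which the promoter of myo-3, a body wall muscle myosin gene, drives GFP fused to DAF-16a. According to the genotype the tagged protein is therefore made in body wall muscle in animals with low insulin signalling. Another label places a GFP-FLAG tag at the C terminus of DAF-16, which differs from the GFP::daf-16a order of the genotype, and the precipitating antibody was directed against GFP. The 2 biological replicates formed 1 group, no second genotype or input library was analysed here, and the comparisons below are between classes of peaks or genes within this group. The files hold peak lists without read counts, so the sequencing depth of each replicate is unknown. Every p-value below treats peaks or genes as units and does not measure variation between animals.

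On the ce11 genome, 2563 peaks passed the threshold on the irreproducible discovery rate (IDR) and are called IDR peaks below. They were the 2563 peaks of highest signal among 30000 candidates called on the pooled replicates, and the remaining 27437 candidates with a summit more than 100 bp from any IDR summit served as the background. The replicate lists held 26922 and 25562 candidates. Of the IDR peaks, 97.4% had a summit within 100 bp in replicate 1, 97.4% in replicate 2 and 94.9% in both (Wilson 95% interval 94.0 to 95.7, 2433 of 2563). Because IDR peaks are the strongest peaks of these same replicates pooled, their high agreement is partly built in and is not an independent check. Membership followed pooled signal, so a single IDR peak need not recur in both replicates. The 2563 strongest candidates of each replicate shared 1774 peaks, against a mean of 81.2 and a maximum of 105 in 100 random draws of as many peaks from the candidate lists. Across the 2433 matched peaks the signals of the replicates had a Spearman correlation of 0.67 and a Pearson correlation of 0.75 on the log10 scale, which describe peaks and not independent samples. Among all candidates of replicate 1, most of them weak, 32.1% had a match in replicate 2. The share of IDR peaks matched in both replicates was 76.1% when summits had to lie within 50 bp.

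**Figure D1:**
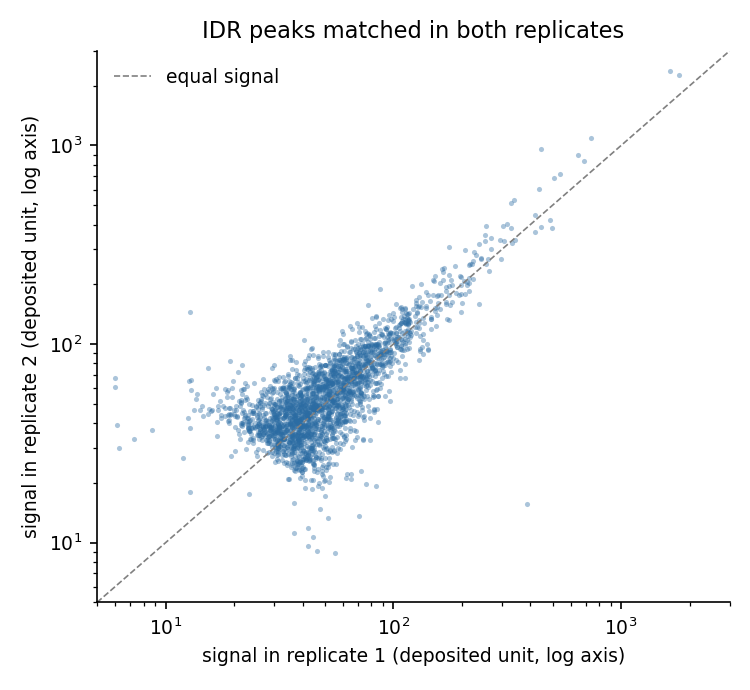
Signal of each IDR peak matched in both replicates, in the unit of the deposited lists, with replicate 1 on the horizontal and replicate 2 on the vertical log axis; the dashed line marks equal signal. The 2433 peaks lie along the line with a Spearman correlation of 0.67, with more scatter at low signal. They come from the strongest peaks of the same replicates pooled and are shown only where both replicates had a match.

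IDR peaks lay mainly in noncoding sequence near gene starts. Location classes were taken from protein-coding genes alone. Intergenic, here and below, therefore means outside protein-coding genes, and such summits may lie in genes of noncoding RNA. Their summits were intergenic in this sense in 63.6% of cases, against 31.9% of the other candidates (log2 odds ratio 1.89 ± 0.06 SE, Fisher's exact test, adjusted p = 5.02e-213). Coding exons held 4.96% of IDR summits against 27.1% of the others, 3' UTRs 1.52% against 5.24% and introns of protein-coding genes 26.7% against 33.0%, all lower by the same test. The share in 5' UTRs, 3.08% against 2.50%, did not pass the test (exact test, adjusted p = 0.0922). From 1000 bp upstream to 200 bp downstream of an annotated gene start lay 67.0% of IDR summits (interval 65.1 to 68.7) and 41.8% of the others (log2 odds ratio 1.50 ± 0.06, two-sided Fisher's exact test, p = 6.47e-133). With the starts of protein-coding genes alone the shares were 47.1% and 30.5% (log2 odds ratio 1.02 ± 0.06).

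The DAF-16 binding element (DBE), TGTTTAC or its reverse complement GTAAACA, occurred within 100 bp of the summit in 229 IDR peaks, 8.93% (interval 7.89 to 10.1), against 2.45% of the other candidates (log2 odds ratio 1.97 ± 0.11, two-sided Fisher's exact test, adjusted p = 1.21e-52 over 10 motifs). The same peaks carried it in 3.16% and 2.93% of the flanks 400 to 600 bp to the left and right (exact sign tests, adjusted p = 4.54e-18 and 1.45e-19). In 5 groups of falling signal the element lay at 10.9%, 10.9%, 7.03%, 9.55% and 6.24% of IDR peaks, not a steady fall, and the strongest group differed from the weakest (log2 odds ratio 0.88 ± 0.33, Fisher's exact test, p = 0.00747). This difference in the DBE was lost when peaks were ordered by the signal of replicate 2 (log2 odds ratio 0.52, exact test, p = 0.104). The DAF-16 associated element CTTATCA, often found near insulin-responsive genes, was at 3.75% and 3.37% (exact test, adjusted p = 0.305).

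Other sequences, several of them shorter, were more common at these summits than the DBE. The DBE had the highest log2 odds ratio of the 10 motifs, 1.97. GAGAGA lay at 40.9% of IDR peaks and at 4428 of the 27437 others (log2 odds ratio 1.85 ± 0.06), and at 10.5% and 10.1% of the left and right flanks. The E-box CAGCTG, bound by the muscle regulator HLH-1, lay at 10.4% and 5.84% (log2 odds ratio 0.91 ± 0.10), and GATA sites at 39.1% and 34.3% (0.30 ± 0.06). GATA sites lay in 35.9% of left and 37.0% of right flanks, and only the left flank differed from the summits (exact sign tests, adjusted p = 0.0317 and 0.172). The MEF2 motif was less common at IDR peaks, 3.39% against 7.30% (log2 odds ratio -1.17 ± 0.16), as was the heat shock element, 9.25% against 11.8% (-0.40 ± 0.10). The SKN-1 motif, at 7.80% and 9.01%, and the reversed DBE and DAE used as control sequences showed no difference from the other candidates past the threshold (exact tests, adjusted p = 0.0603, 0.0613 and 0.204). The SKN-1 motif was less common at the summits than in either flank, 9.60% in each (exact sign tests, adjusted p = 0.0353 and 0.0448). Of all 8192 sequences of 7 bases, counted with their reverse complements, 1753 were enriched and 1377 depleted (Fisher's exact test, Benjamini-Hochberg). The 10 with the smallest p were AGAGAGA, CTCTCTC, CGAGAGA, AGAGACG, AGAGAAA, ACGCAGA, CTGCGTC, GAGACGC, AGACGCA and AAGAGAG, and AGAGAGA occurred at 20.6% of IDR peaks against 6.76% of the others. The DBE ranked 15 by p. Its share at IDR peaks was 3.65 times that of the others, between 3.75 for CGAGAGA and 3.04 for AGAGAGA. The test of 7-base sequences was not repeated against candidates matched on GC content and location. Its calls may therefore partly reflect where IDR peaks lie.

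**Figure D2:**
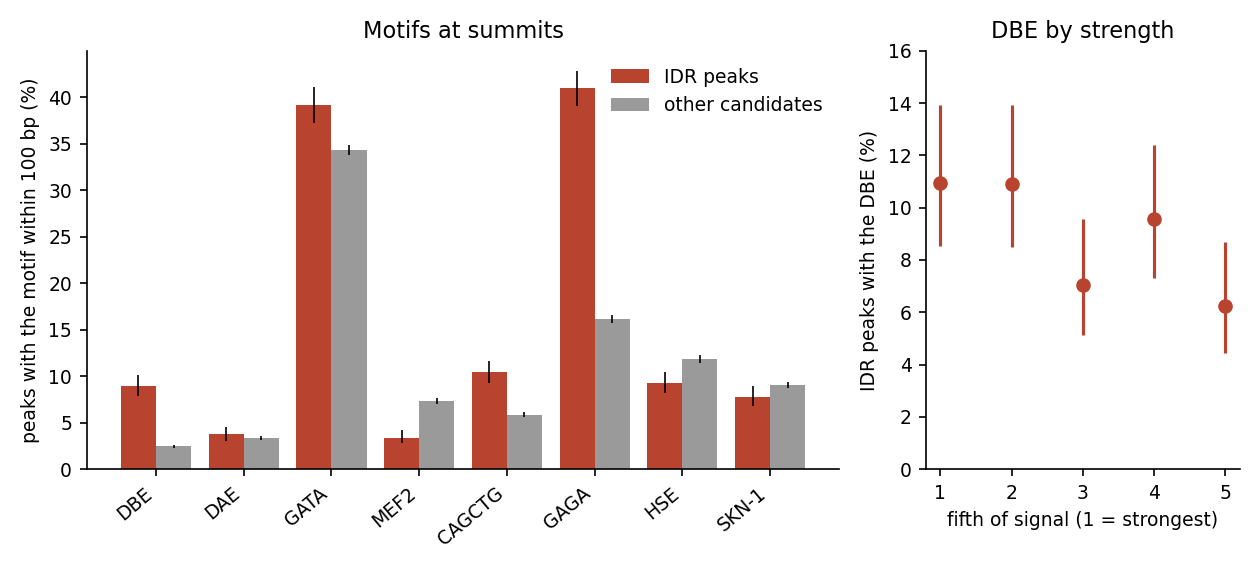
Left, percentage of IDR peaks and of other candidates with each motif within 100 bp of the summit; right, percentage of IDR peaks with the DBE in 5 groups of falling signal; bars and points are shares with Wilson 95% intervals. The DBE is at 8.93% against 2.45% and at 10.9%, 10.9%, 7.03%, 9.55% and 6.24% of the groups from strongest to weakest, while GAGAGA is at 40.9% of IDR peaks.

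Genes of body wall muscle, cytosolic ribosomal proteins, chaperones and central carbon metabolism were bound more often than other genes. A gene was called bound when an IDR summit lay in its promoter window, and the background was the 6580 nuclear protein-coding genes with any candidate there, of which 1249 were bound. Of 24 gene lists, these 4 were bound more often and none less often (two-sided Fisher's exact test, Benjamini-Hochberg over the lists). Of the body wall muscle list, 19 of 34 genes were bound (55.9%, interval 39.5 to 71.1, log2 odds ratio 2.45 ± 0.50, exact test, adjusted p = 2.06e-05). The strongest peaks among them lay at act-1, an actin (V:11080621, signal 267), tnt-2 and mup-2, which encode troponin T (X:8724123, signal 237, and X:6410583, signal 227), and unc-78, an actin-interacting protein (X:3412137, signal 196), all upstream of the gene in intergenic sequence. Without peaks holding a 31-base sequence that occurs again in the genome, 19 of 34 genes of this list were still bound. The muscle myosin genes myo-3 and unc-54, the paramyosin gene unc-15, the troponin C gene pat-10 and hlh-1, the MyoD homologue, were also bound. The promoter of myo-3 is also in the transgene, and the test of this list was not repeated without it.

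Ribosomal protein genes were bound in 31 of 66 cases (47.0%, interval 35.4 to 58.8, log2 odds ratio 1.95 ± 0.36, exact test, adjusted p = 4.67e-06). Their strongest peaks, all intergenic, were at rpl-3 (III:3867579, signal 677), rpl-20 (IV:4750067, signal 431), rpl-15 (IV:654930, signal 376) and rpl-35 (III:7854686, signal 338). Of chaperones and heat shock proteins, 16 of 30 were bound (53.3%, interval 36.1 to 69.8, log2 odds ratio 2.30 ± 0.53, exact test, adjusted p = 2.03e-04). They were led by hsp-70 (I:9322674, signal 357, with a DBE, in an intron of the neighbouring uggt-2), dnj-13 (II:11545503, signal 357, in an intron of dhgd-1), hsp-110 (III:8447165, signal 318) and hsp-60, the mitochondrial chaperonin (III:1619128, signal 270). Of central carbon metabolism, 7 of 13 genes were bound (53.8%, interval 29.1 to 76.8, log2 odds ratio 2.32 ± 0.80, exact test, adjusted p = 0.0308). The strongest were icl-1, the glyoxylate cycle enzyme (V:728086, signal 161), gpd-2, a glyceraldehyde-3-phosphate dehydrogenase (X:3115250, signal 94.2, in an intron of mai-1), aldo-1, an aldolase (III:13565046, signal 80.8), and pgk-1, phosphoglycerate kinase (I:3867454, signal 78.1). Assigning each summit to the nearest gene start ended the call of ribosomal proteins (log2 odds ratio 0.85, exact test, adjusted p = 0.226) and of chaperones (0.94, p = 0.245). In the 1282 IDR peaks of highest signal alone the calls of body wall muscle (1.49, exact test, adjusted p = 0.0636) and carbon metabolism (2 of 13, 0.72, p = 0.818) were lost. That of carbon metabolism was also lost without replicate 2 (1.71, exact test, p = 0.105) and in the window from 500 bp upstream to 100 bp downstream (2.02, p = 0.127).

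**Figure D3:**
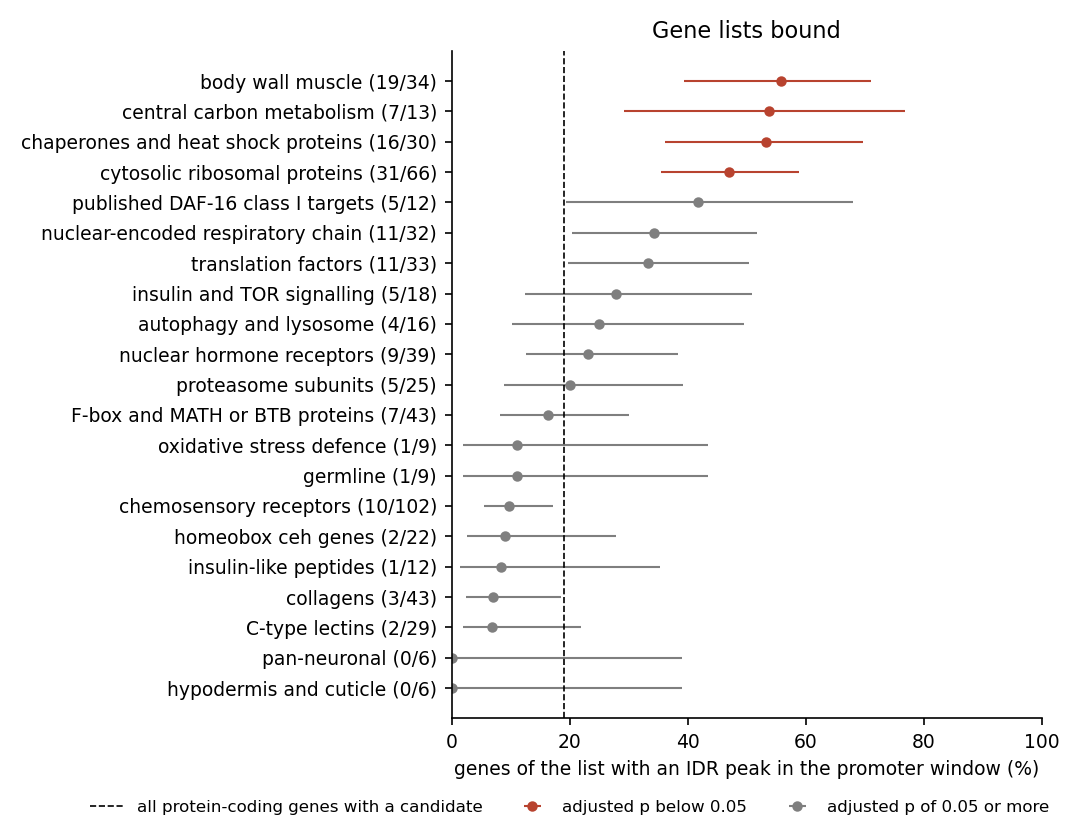
Percentage of each list's genes with an IDR peak in the promoter window, among its members with any candidate there, with Wilson 95% intervals; lists with fewer than 5 such members are left out, and the numbers in brackets are genes bound and genes with a candidate. The dashed line marks the share of all protein-coding genes with a candidate, 1249 of 6580, and the 4 lists that passed the test lie between 47.0% and 55.9%.

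Of the DAF-16 class I targets, genes that earlier studies found to be activated by DAF-16, 12 had a candidate and 5 were bound (41.7%, exact test, adjusted p = 0.159). These were djr-1.2 (V:4055755, signal 166, with a DBE), icl-1, the small heat shock protein gene hsp-12.6 (IV:9447397, signal 148), the linker histone gene hil-1 (V:14948829, signal 126, with a DBE) and gpd-2. The list passed the test in the stronger IDR peaks (log2 odds ratio 2.71, exact test, adjusted p = 0.0332) and against all protein-coding genes (1.98, p = 0.0325). The superoxide dismutase gene sod-3 had a candidate of signal 24.4 (rank 8597 of the pooled list) and the metallothionein gene mtl-1 of signal 15.1 (rank 17087), and neither was an IDR peak. Of the 10 class II targets, repressed by DAF-16 in earlier studies and including dod-24, none had a candidate in the window, nor had pqm-1, a transcription factor linked to class II genes. In insulin and TOR signalling 5 of 18 genes were bound: the kinase genes akt-2 (X:14146990, signal 175) and akt-1 (V:10248728, signal 93.2), ftt-2, a 14-3-3 protein (X:11606181, signal 171), rict-1, the Rictor homologue (II:13117345, signal 108), and ist-1 (X:7126555, signal 86.0), with an adjusted p of 0.793 by the exact test.

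Genes typical of other tissues were seldom bound, but few had a candidate. None of 3 intestinal, 6 hypodermal, 6 neuronal and 1 pharyngeal muscle genes with a candidate was bound, and 1 of 9 germline genes was, cgh-1, an RNA helicase gene (exact tests, adjusted p of 1, 0.850, 0.850, 1 and 1). Of the nuclear-encoded respiratory chain 11 of 32 genes were bound, led by cox-5A, cox-6A, cox-5B and atp-1, and of translation factors 11 of 33, led by iff-2, eif-2Bgamma, eef-1G and eif-3.C (exact tests, both adjusted p = 0.147). Shares near the background were seen for proteasome subunits (5 of 25, rpn-3, rpn-6.1, rpn-2, rpn-9 and rpn-11), autophagy and lysosome genes (4 of 16, atg-18, lgg-2, lgg-1 and lmp-1), nuclear hormone receptors (9 of 39, led by nhr-68, nhr-1, nhr-48 and nhr-47) and F-box, MATH or BTB genes (7 of 43, led by fbxb-58, bath-36, fbxb-72 and fbxb-85). Lower shares that did not pass the test were those of chemosensory receptors (10 of 102, led by srh-2, srbc-5, srh-269 and sre-23, Fisher's exact test, adjusted p = 0.0730), collagens (3 of 43, col-63, col-185 and col-165, adjusted p = 0.147), C-type lectins (2 of 29, clec-126 and clec-57), homeobox ceh genes (2 of 22, ceh-38 and ceh-20), insulin-like peptides (1 of 12, ins-39) and oxidative stress defence (1 of 9, the catalase gene ctl-3). With the nearest gene start chemosensory receptors and collagens were bound less often than other genes, and chemosensory receptors also without peaks of repeated sequence. Some peaks serve a pair of divergent genes, such as icl-1 and srh-2, or hsp-110 and rpn-3, and cannot be assigned to either.

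Genes of small RNAs were bound more often than protein-coding genes. Of transfer RNA genes with a candidate in the window, 231 of 488 were bound (47.3%, interval 42.9 to 51.8, log2 odds ratio 1.94 ± 0.14, exact test, adjusted p = 6.12e-41 over 7 classes). The shares were 97 of 240 for small nucleolar RNA genes (40.4%, log2 odds ratio 1.53 ± 0.20, exact test, adjusted p = 2.53e-13), 22 of 55 for small nuclear RNA genes (40.0%, 1.51 ± 0.40, p = 6.60e-04) and 713 of 3058 for genes annotated as ncRNA (23.3%, 0.38 ± 0.08, p = 2.63e-06). Micro RNA genes (27 of 110) and long intergenic RNA genes (17 of 72) did not pass the test, and the 1 ribosomal RNA gene with a candidate was not bound. Transfer RNA genes exist in many near-identical copies, so their peaks are uncertain. Without peaks holding a 31-base sequence that occurs again in the genome, 23 of 155 transfer RNA genes were bound (14.8%, log2 odds ratio -0.43, exact test, adjusted p = 0.283) and the ncRNA call was also lost (0.11, p = 0.283), while small nucleolar RNA genes stayed at 87 of 217. The call of small nuclear RNA genes was lost without replicate 1 (19 of 59, log2 odds ratio 0.92, exact test, adjusted p = 0.0564).

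IDR peaks were concentrated on the X chromosome. It held 732 of the 2540 nuclear IDR peaks, 28.8% (interval 27.1 to 30.6), against 18.3% of the other candidates and 17.7% of the nuclear genome length. The log2 odds ratio of X against the autosomes was 0.86 ± 0.07 (two-sided Fisher's exact test, p = 7.86e-35). Chromosomes I, II, III and IV held smaller shares of IDR peaks than of other candidates, between 13.6% and 14.1% against 15.8% to 18.1% (exact binomial tests, largest adjusted p = 0.00890), and chromosome V, 15.9% against 14.6%, did not pass (p = 0.0720). Against genome length, IV (14.1% against 17.4%, exact binomial test, adjusted p = 1.06e-05) and V (15.9% against 20.9%, p = 5.20e-10) held fewer IDR peaks, while I, II and III did not pass (p = 0.0562, 0.0562 and 0.908).

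**Figure D4:**
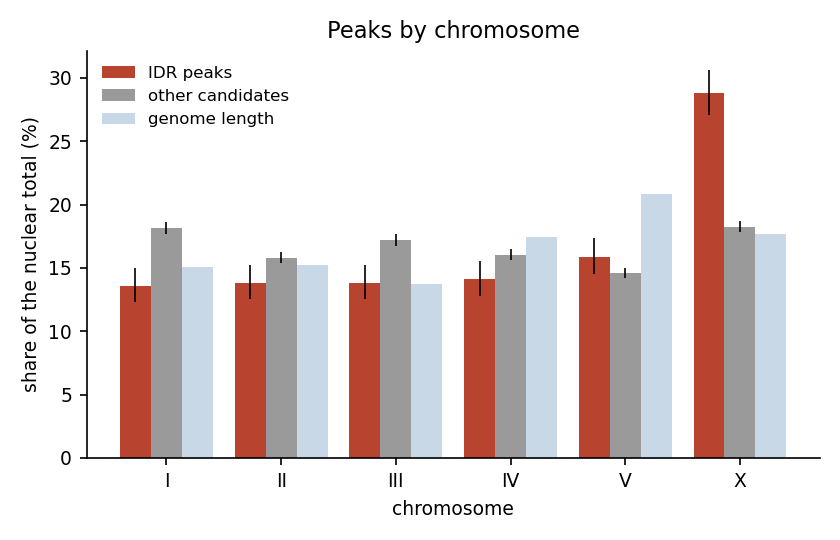
Share of nuclear IDR peaks, of other candidates and of genome length on each chromosome, in percent, with Wilson 95% intervals on the peak shares. The X chromosome holds 28.8% of IDR peaks against 18.3% of the other candidates, while chromosomes I to IV hold 13.6% to 14.1%.

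Of the 25 strongest IDR peaks, 16 lay on the mitochondrial genome, and 6 of the 9 nuclear ones on X. The mitochondrial ones were summits within the broad regions M:502-6676, M:6714-10633 and M:10588-13408, so they cannot be read as separate sites. The strongest nuclear peak, at V:12235443-12235912 with its summit at 12235686 and a signal of 865 (417 in replicate 1 and 445 in replicate 2), was intergenic, 1343 bp upstream of myo-3. It was followed on X by peaks nearest to ttr-48 (summit X:3839462, signal 712), ZK899.6 (X:9465861, signal 712, with a DAF-16 associated element), F19H6.5 (X:12363124, signal 694, in the 3' UTR of F19H6.6), nspc-17 (X:14525903, signal 648), W02H3.3 (X:11094216, signal 633) and K02D3.1 (X:13700882, signal 611). On chromosome III lay rpl-3 and an intergenic peak 4663 bp from F22B7.9 (III:8658588, signal 627), the only one of the 9 with a DBE. Among the 25 strongest nuclear peaks, a set chosen after the values were seen, 16 lay on X, 16 were intergenic and 2 held a DBE. They included 2 peaks in introns of fkh-7, a forkhead gene (IV:5594051, signal 561, and IV:5588498, signal 518).

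The genes named in the genotype and those of common transgene parts were examined for their values alone. In the promoter window of myo-3 an IDR peak lay 500 bp upstream of the start (V:12234843, signal 169), between the strong peak at -1343 and another in the gene at +735 (V:12233608, signal 81.0). At daf-16 the window held a candidate of signal 44.0 that was not an IDR peak, and IDR peaks lay at -2279 (I:10748219, signal 67.0) and +1283 (I:10751781, signal 82.3). At daf-2 the strongest candidate of the window had a signal of 9.95, and 1 IDR peak lay within the gene (III:3031584, signal 132). At unc-54, a body wall muscle myosin gene, IDR peaks lay at -132 (I:14863614, signal 91.5), at -1633 (I:14865115) and near the 3' end (I:14855963, signal 217). No candidate lay in the window of unc-119. Reads from the transgene's own copy of the myo-3 promoter would add to the native locus, and the lists cannot separate them. At daf-16 the same holds for daf-16a outside the deletion of the strain. Within the deletion, by the genotype, only the transgene could give reads. The deleted part was not mapped here, so it is unknown which of these peaks lie in it.

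**Figure D5:**
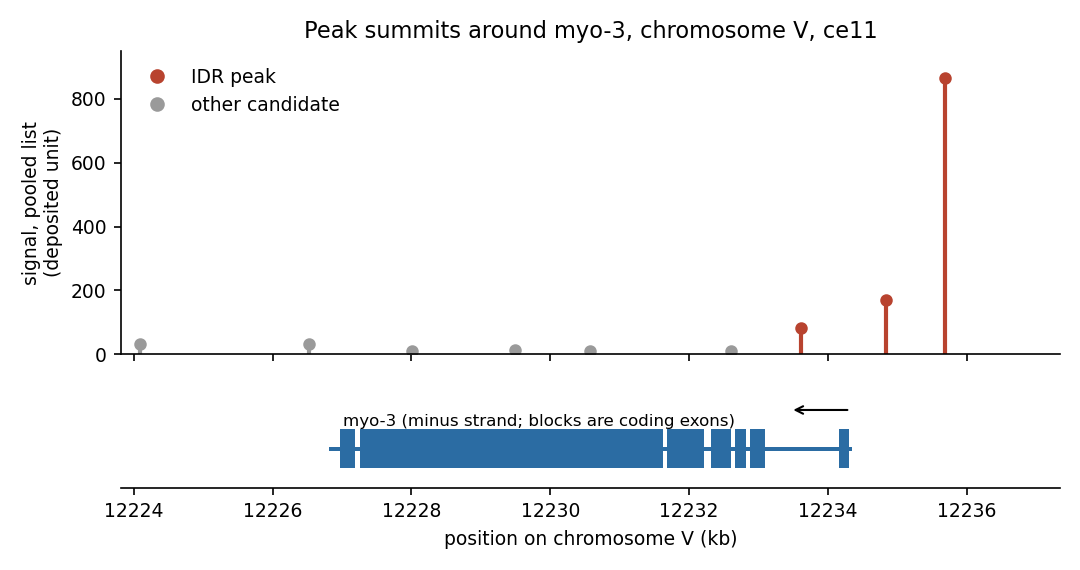
Peak summits of the pooled list around myo-3 on chromosome V of ce11, with position in kb on the horizontal axis and signal in the deposited unit on the vertical axis; coloured points are IDR peaks and grey points other candidates, above the gene model. The 3 IDR peaks have signals of 81.0, 169 and 865, and the highest lies 1343 bp upstream of the start.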

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

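Signal on the mitochondrial genome stood out, which the comparisons of genes and chromosomes left out. All 23 pooled candidates on it were IDR peaks, with 23 candidates in replicate 1 and 22 in replicate 2, and their regions covered 13169 of its 13794 bp. Their median signal was 850 against 93.7 for nuclear IDR peaks, and the strongest reached 4066. The genes of this genome with such a summit in their window included COX3 and ND1, subunits of the respiratory chain. The mitochondrial peaks made up 0.897% of IDR peaks, and 1 of the 23 held a DBE. Signal over nearly the whole of this genome does not mark single binding sites. The control library was not analysed, so the source of this signal was not tested.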

How the results depend on the processing

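Of the 61 recomputed values of the main results under an alternative, 52 stayed on their side of the threshold or, for counts, within 1.5 times the main count, whichever lists made it up, and for other values within their 95% interval. No log2 odds ratio among them reversed. Counts and agreement shares could not be scored as reversed. Behind the count of noncoding classes, the log2 odds ratio of tRNA genes went from 1.94 to -0.43 without peaks holding a repeated 31-base sequence. Of the 4 gene lists bound more often, 2 were kept with the nearest gene start, where 2 others were lower, and 2 in the stronger IDR peaks. Alternatives named as added in the account of the processing were chosen after the data were seen. The promoter, DBE and X results passed their tests under all of their alternatives, with log2 odds ratios of 1.02 to 1.72, 1.27 to 2.19 and 0.69 to 0.92. The number of IDR peaks was 3353 on ce10 against 2563 on ce11, and 1282 among the stronger IDR peaks, by construction. The lowest signal of an IDR peak was 49.6 on ce10 and 60.5 on ce11, so calls of candidates near these values depended on the build. The promoter, motif and gene list tests were not run on the ce10 lists. Agreement of both replicates, which the selection of IDR peaks favours, was 76.1% at 50 bp, 99.5% at 200 bp and 82.2% with a reciprocal overlap of 50%. It was 92.8% on ce10 and 97.97% in the stronger IDR peaks. The DBE difference between strong and weak peaks fell to a log2 odds ratio of 0.52 with the signal of replicate 2, and the cause was not tested. With all protein-coding genes as background, 12 gene lists passed in place of 4, 8 of them higher and 4 lower, since genes without a candidate then entered. Without peaks holding a repeated 31-base sequence, 2 noncoding classes passed in place of 4. Depth is unknown, so no limit from it can be given. No paired analysis was possible because the samples form 1 group.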

Other observations

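The tests of copies of ribosomal protein genes, of the DBE and of repeated sequence in separate gene classes, of muscle genes against other tissues and of the motif core in the 25 strongest X peaks were chosen after the result was seen. So were the genes named in the next paragraph and its tests of DBE peaks by gene list and by location.

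The strongest nuclear IDR peaks with a DBE included the intergenic peak near F22B7.9 and one in an intron of pqn-62 (X:5197640, signal 556). Further DBE peaks lay at tts-1, a long noncoding RNA gene (X:1504938, signal 416), in introns of fkh-7 (IV:5604738, signal 410) and aakg-4, a subunit gene of AMP-activated kinase (X:2316330, signal 334), and at trp-1, a channel gene (III:8534847, signal 319), idhg-1, an isocitrate dehydrogenase subunit gene (III:4568544, signal 240), and sqrd-1, a sulfide quinone oxidoreductase gene (IV:14219900, signal 227). Tested by gene list, binding by DBE peaks passed the adjusted threshold in none. It was highest in class I targets (djr-1.2 and hil-1, 2 of 12 genes, log2 odds ratio 3.49 ± 1.13) and central carbon metabolism (ipgm-1 and fbp-1, 2 of 13, 3.35 ± 1.12; exact tests, p = 0.0184 and 0.0215, both adjusted p = 0.258), too few genes to decide. IDR peaks with and without a DBE showed no difference past the threshold in their share on X (31.0% and 28.3%, Fisher's exact test, adjusted p = 0.701), in introns (29.3% and 26.5%, p = 0.701) or with GAGAGA (40.6% and 41.0%, p = 1). Those with a DBE lay less often at tRNA, snoRNA or snRNA genes, 6.11% against 13.4% (exact test, adjusted p = 0.00934).

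The excess on X (log2 odds ratio 0.86) was weighed against 4 sources. It was 0.77 against candidates matched on GC content and promoter location (95% bounds 0.58 to 0.96). Without peaks at small RNA genes, which left 615 of the 732 IDR peaks on X, it was 0.79. Neither of these changes removed it. It was 0.82 without peaks holding GCGCAGGG, the core of a motif of recruitment sites of the dosage compensation complex, and 0.86 among peaks without a DBE. These filters left 714 and 661 of the 732 peaks, so they took out too few to remove the excess in any case. They show only that peaks with the core or with a DBE are not the whole excess. The core also marks only some recruitment sites, so such sites stay open as a source. The core lay in 10 of the 25 strongest IDR peaks on X and in 8 of the other 707 (log2 odds ratio 5.86 ± 0.78, Fisher's exact test, p = 1.07e-11), so the strongest X peaks may in part be recruitment sites of that complex. Whether DAF-16 or another feature of such chromatin gives this signal was not tested, since no control library or second factor was analysed.

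At peaks of tRNA, snoRNA and ribosomal protein genes the DBE was less frequent than at other IDR peaks, 15 of 328 against 214 of 2235 (log2 odds ratio -1.14 ± 0.40, Fisher's exact test, p = 0.00183). At tRNA and snoRNA genes alone the element was also less frequent (14 of 304 peaks, -1.12 ± 0.41), where binding through it predicted an equal or higher share. At ribosomal protein genes 1 of 29 peaks (-1.47 ± 1.47) is too few to tell. Most other IDR peaks lack the element too, so a lower share cannot show what gives the signal. Of IDR peaks at tRNA, snoRNA or snRNA genes, 60.6% held a repeated 31-base sequence, which leaves their positions uncertain. Without peaks of repeated sequence, ribosomal protein genes were still bound more often than other genes (30 of 65, 1.89 ± 0.36), as were snoRNA and snRNA genes (1.50 ± 0.19), so shared reads are not their whole source, but the value for tRNA, snoRNA and snRNA genes together fell from 1.79 ± 0.11 to 0.88 ± 0.16. For tRNA genes it was then -0.43 (95% bounds -1.08 to 0.21), and shared reads may explain their excess, but of 421 tRNA genes with a candidate within 100 bp only 32 kept one and 9 of these had an IDR peak, which leaves it open. Highly transcribed, open chromatin is a further explanation that was not tested.

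Body wall muscle genes, the tissue in which the genotype places the tagged protein, were bound more often than genes of the 5 other tissue lists with a candidate, 19 of 34 against 1 of 25 (log2 odds ratio 4.93 ± 1.55, Fisher's exact test, p = 1.95e-05). This argues against tissue-restricted expression in general as the source, but only among genes with a candidate. The comparison rests on 25 genes of the other tissue lists, and most members of those lists had no candidate. It also counts myo-3, whose promoter is in the transgene, and was not repeated without it. None of the 22 peaks at muscle genes held a DBE, against 229 of the other 2541 (log2 odds ratio -2.16 ± 2.07, exact test, p = 0.253), which is too few to tell whether binding goes through the element. Binding in muscle itself may explain the pattern, as may open muscle chromatin in whole animals, and no control analysed here separates them.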
